A study of Mus musculus with 4 samples.

How the data were processed

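The files hold raw UMI counts per gene and spot barcode, which the authors deposited without normalisation, for 4992 barcodes and 32285 genes in each of 4 libraries. Per the submitters' processing notes, reads were aligned to mm10 and counted with Space Ranger, and per the file headers the matrices were written by software version Cell Ranger 4. The version of Space Ranger and the release of its gene annotation are not given in the sources used here. The files list every barcode of the slide area. Spot positions and images were not analysed here, so no spot was placed in the section, and no call of spots over tissue was used. Spots with at least 1000 UMIs were kept, which held 98.6%, 99.3%, 99.5% and 99.5% of UMIs in control 1, control 2, knockout 1 and knockout 2. The 78 duplicated gene symbols were kept apart by their identifiers. Gene positions came from a table of 26335 symbols on GRCm38.p6.

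Groups were taken from the genotype in the labels, 2 libraries each. Gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except for the alternatives named as added. The lists cover the CCM complex, CCM lesion vascular genes, pan-endothelial, blood-brain barrier, mural, fibroblast and matrix genes, reactive and general astrocytes, homeostatic and activated microglia, complement, antigen presentation, interferon response, chemokines, coagulation, platelets, neutrophils, monocytes and border macrophages, lymphocytes, iron and heme, erythrocytes, hypoxia, angiogenesis, ependyma, choroid plexus, leptomeninges, myelin, oligodendrocyte precursors, disease-associated oligodendrocytes, excitatory and inhibitory neurons, synapse, immediate early genes, heat shock and ER stress, cell cycle, cholesterol synthesis, lysosome, oxidative phosphorylation and mitochondrial transcripts. The list genes 1500015O10Rik, Clec7a, Ero1a, Mx1 and Rigi were not analysed here, because the files do not list them under these symbols. Results for some genes are not reported here. Region lists cover cortex, hippocampus, striatum, thalamus, hypothalamus and amygdala, midbrain and hindbrain, cerebellum, olfactory bulb and white matter.

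Counts of kept spots were summed per library and tested in R 4.3.3 with edgeR 4.0.16, using TMM factors (0.988, 0.962, 1.01 and 1.04 in the order above), filterByExpr and the quasi-likelihood test, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Log2 fold changes are knockout over control, CPM values use the library total times its TMM factor, and standard errors come from the fitted change and its test statistic. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and again with an estimated one, and with fry. The number of list members that passed was also counted with p adjusted over the list alone. The rule named the 12 largest rises, the 12 largest falls and the 6 smallest p among genes past the threshold with libraries of the groups apart and a mean of at least 5 CPM over the 4 libraries, which 4484 genes met, 160 of them with predicted symbols that were not named. It added Pdcd10, up to 4 list members past the threshold with the smallest p per list (2 with a mean of at least 5 CPM where fewer than 2 passed), 5 genes per region, 10 for the region-matched sums and 10 per class of spots.

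Spots were clustered in scanpy 1.11.5 with leidenalg 0.10.2 under Python 3.11.15, after scaling each to 10000 UMIs and log transformation, on 2000 variable genes with the 768 list genes and the mitochondrial, ribosomal and haemoglobin genes left out, 30 principal components, 15 neighbours, a Leiden resolution of 0.5 and seed 0. A region was named by the region list with at least 3 genes among its 50 leading genes, and left unnamed where other leading genes spoke against the name. Regions with at least 50 spots in every library were tested, and region-matched sums drew equal numbers of spots per region and library, each spot thinned to 1000 UMIs. After the clusters were seen to part by group, an added assignment gave each spot of at least 5000 UMIs to the region list with the highest mean z score, with genes of tested lists left out and at least 5 genes per list, which the white matter list did not have.

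Vessel-rich spots were the top 10% of a library's spots by share of pan-endothelial UMIs, and the test was the interaction of genotype with spot class, blocked by library, with genes of that list left out of the calls. For shares of spots, spots of at least 5000 UMIs were thinned to that number, and the limit was the higher of the controls' 99th percentiles, with 95% Wilson intervals. Genes of spots above the limit of the CCM lesion vascular list were tested against other spots of the same library with the library as a block and genes of that list left out of the calls. Other tools were DESeq2 1.42.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

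The procedure was tested on simulated counts with the mean levels and totals of these libraries and a dispersion common to all genes. Genes were drawn independently, and no difference in regions was simulated. The false calls below therefore do not bound those in the real data, and the list result does not test the preset correlation. Over whole sections 90% of 2-fold and 73.7% of 1.5-fold changes were called, with 3 false calls among 17339 genes. For region-matched sums it was 28.7% and 9.20% (1 false call among 3119 genes), for vessel-rich spots 56.9% of 2-fold changes (4 among 16749) and for lesion-score spots 76.8% (6 among 16212). A raised lysosome list had a camera adjusted p of 4.59e-121, and no other list without shared genes, 34 in number, passed. Alternatives were DESeq2, RLE factors, no filter on low counts, other limits on UMIs per spot, thinned spots, leaving out each library, the replicate number as a block, other cluster settings, other limits for spot classes and, for lists, fry, an estimated correlation and matched sums. Where a library was left out, the lone library of its group was assumed to vary like the other group. Alternatives added after the data were seen were spots of at least 5000 UMIs, the region-list assignment, the lesion list without Ly6a and Cdh2, and a block with crossed numbers.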

Results

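Spatial transcriptomes were measured on 10 µm sections of fresh-frozen mouse brain with 10x Visium, which captures RNA on barcoded spots that each cover several cells. Pdcd10, also called Ccm3, encodes an adaptor protein whose loss from endothelium gives rise to cerebral cavernous malformations, clusters of dilated and leaky vessels. In the knockout mice the floxed gene was deleted in brain endothelial cells by Slco1c1-iCreERT2, a Cre recombinase switched on with 50 µg of 4-hydroxytamoxifen on postnatal day 1, and the brains were taken on day 65. Littermates with the floxed gene and no Cre were the controls. There were 2 control and 2 knockout libraries, and the series asks which inflammatory and clotting genes change in brains with such lesions. The titles and the design text place all 4 libraries in normoxia, while a treatment label calls the knockouts hypoxic and the controls normoxic, and the treatment protocol of all 4 gives 12% oxygen for 2 days. If the hypoxia label holds, oxygen level coincides with genotype in every library, and each difference below compares both at once. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

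The deposited counts totalled 50148764 and 64317838 UMIs (unique molecular identifiers) in controls 1 and 2, and 53514669 and 74467027 in knockouts 1 and 2. Spots with at least 1000 UMIs were kept, which left 2931 and 4096 spots in the controls and 4599 and 4472 in the knockouts. The median kept spot held 15326 and 16226.5 UMIs in the controls, and 8158 and 13164.5 in the knockouts. Mitochondrial genes took 7.43% and 11.4% of control UMIs and 8.52% and 8.17% of knockout UMIs. Across genes, log2 CPM (counts scaled to 1e6 per library) of the controls correlated at r = 0.994 and that of the knockouts at r = 0.997, against 0.956 to 0.961 between groups. Genes are not independent replicates, and both pairs differed by more than sampling noise, with chi-square values per degree of freedom of 81.0 for the controls and 24.0 for the knockouts.

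Pdcd10, the targeted gene, lies on chromosome 3 from 75516490 to 75556852 (GRCm38.p6, the same build as mm10). Its level was 90.9 and 82.3 CPM in the controls and 80.3 and 83.0 CPM in the knockouts. The log2 fold change of -0.08 (SE 0.0751) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p 0.410). A 3′ tag may lie outside the deleted part of the gene, and the deletion is confined by design to endothelial cells, which give a small share of a spot's RNA, so this value checks nothing about the labels.

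Clustering parted the spots of control and knockout sections. Done jointly on genes outside the lists tested here, it gave 16 regions, and the shares of spots per region overlapped by only 5.97% between the groups, against 83.5% between the controls and 89.9% between the knockouts. Regions led by Prkcd, Tnnt1 and Plekhg1 (named by the thalamus list) or by C1ql2 and Prox1 (hippocampus list) came from control sections, and regions led by Cartpt, Ucn and Scn4b (midbrain and hindbrain list) or Slc6a5, Ecel1 and Sdcbp2 (olfactory bulb list) almost wholly from knockout sections. The hippocampus list also named a region of knockout sections alone, led by Penk, Plekha2 and Vgll3. The olfactory bulb name rests on 3 genes of that list, the fewest the naming rule allows. The leading genes of the same region included 2 of the hippocampus list and 1 of the midbrain and hindbrain list. The name therefore need not mean that knockout sections held olfactory bulb. Serpina3n and Vim, which the clustering did not use, were among the leading genes of a region with 26.1% and 25.8% of knockout spots and 0% of control spots. With expression centred per library the overlap between groups was 44.9%. When spots of at least 5000 UMIs were assigned instead to the fixed region list they scored highest on, it was 79.9%. By that assignment the thalamus list took 15.9% and 17.8% of control spots and 8.57% and 7.81% of knockout spots. The cortex list took 23.2% and 23.7% against 17.8% and 18.4%, the striatum list 5.78% and 4.81% against 10.9% and 8.85%, and the midbrain and hindbrain list 11.3% and 9.39% against 16.9% and 15.1%. An exact permutation test of 2 against 2 libraries cannot give a two-sided p under 0.33, so these shares are given without a call. The high overlap within groups argues against a parting by single libraries. Whether the clusters part by the brain regions in the sections, by genotype or by another trait shared within a group was not settled. Pituitary hormone genes were almost absent from the knockouts, as given below. The sections therefore differed at least in the pituitary RNA they held, which enters the whole-section differences below, and a difference in brain regions may enter them too.

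Over whole sections, the 12 largest rises in the knockouts included genes of acute-phase, matrix and phagocyte proteins. Timp1, an inhibitor of matrix metalloproteinases, was at 36.2 ± 0.390 CPM (SD, n = 2) in the knockouts and 0.623 ± 0.0749 in the controls, a log2 fold change of 5.87 (SE 0.115). The protease inhibitor Serpina3n, a marker of reactive astrocytes, went from 16.9 ± 2.31 to 394 ± 3.28 CPM, 23.2-fold, and Lcn2, an iron-binding acute-phase protein, from 0.939 ± 0.177 to 35.8 ± 5.03, 38.6-fold. Gpnmb and Lgals3, expressed by phagocytic macrophages and microglia, rose 20.7-fold and 17.3-fold, and the monocyte gene Ms4a6c rose 24.9-fold. The interferon-induced chemokine Cxcl10 was at 0.246 and 0.244 CPM in the controls but at 3.17 and 21.0 in the knockouts, so that its 5.64 log2 change had an SE of 1.05. Col5a3 (log2 fold change 4.23) and the lipid-droplet gene Plin4 (4.41) completed the rises together with Ucn (5.73), Slc6a5 (5.38) and Sdcbp2 (24.3-fold), which also led regions seen in knockout sections. Adjusted p of these 12 genes ran from 2.64e-06 for Timp1 to 0.00589 for Cxcl10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

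The largest falls were led by genes of the pituitary and choroid plexus. The pituitary hormone genes Prl, Gh and Cga were at 69.5, 80.9 and 42.7 CPM in control 1 and at 11.4, 40.7 and 6.79 in control 2, and none exceeded 0.0742 CPM in a knockout library, where counts were too few for a useful fold. Ttr, the transthyretin gene of choroid plexus, was at 120 and 42.4 CPM in the controls and 0.501 and 0.598 in the knockouts. The arterial gene Gkn3 (log2 fold change -6.00) and the neuropeptide genes Agrp (-5.21), Pth2 (-4.95) and Cort (-4.40) fell too. The oligodendrocyte gene Opalin fell from 88.4 ± 5.58 to 9.64 ± 0.120 CPM (log2 fold change -3.20), and the activity-induced transcription factors Egr2, Egr4 and Nr4a1 fell by 3.81, 2.63 and 2.60 on the log2 scale. In all, 6739 of 17546 tested genes passed edgeR's quasi-likelihood test, 3532 higher and 3207 lower, and 1941 of them changed at least 2-fold, 1399 up and 542 down. Of the genes tested, 12722 had both knockout libraries beyond both control libraries, where chance alone gives 33.3% of genes. The smallest p-values belonged to Timp1, Fbln5 (log2 fold change 3.28), Serpina3n, Opalin, Spp1 (3.04) and Pglyrp1 (2.98). With every kept spot thinned to 1000 UMIs, 3193 of 13317 genes passed, and Siglech (edgeR adjusted p 0.0550), Itgb3 (0.112) and Ighm (0.0521), named below, did not.

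**Figure D1:**
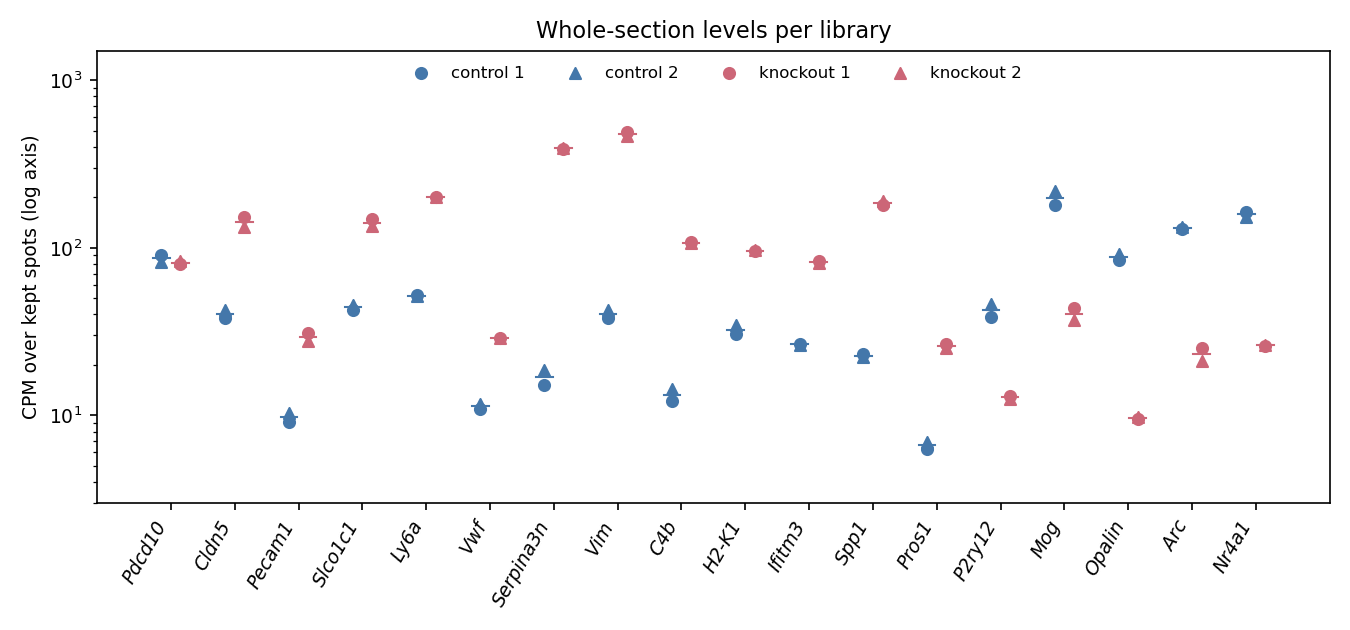
CPM over kept spots (log axis) of 18 genes in the 4 libraries, with points for libraries and a line at each group's mean. Pdcd10 lies at 80.3 to 90.9 CPM in all 4 libraries, Serpina3n at 391 and 396 CPM in the knockouts against 15.3 and 18.5 in the controls, and Opalin at 9.55 and 9.72 against 84.5 and 92.4.

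Vascular genes rose as a group. Of the 14 tested pan-endothelial markers 12 rose and 0 fell, with 12 passing when adjusted over the list alone and a list median of 0.86 on the log2 scale (camera adjusted p 1.04e-06, and adjusted p = 0.405 with an estimated correlation). Cldn5, the tight-junction claudin of brain endothelium, rose from 40.3 ± 2.99 to 143 ± 14.4 CPM, Pecam1 rose 3.02-fold and Esam 2.26-fold. Of 25 genes in the CCM lesion vascular list, taken from knowledge of such lesions before the data were examined, 17 rose and 2 fell, and 19 passed when adjusted over the list alone (median 0.97, camera adjusted p 1.04e-06, and adjusted p = 0.284 with an estimated correlation). Among them Procr, the endothelial protein C receptor, rose 14.6-fold, Ly6a 3.90-fold, the nitric oxide synthase Nos3 2.84-fold and Vwf, the von Willebrand factor, 2.56-fold. The angiogenesis list had 19 rises and 6 falls among 36 genes, 27 passing over the list alone, with Angpt2 up 8.48-fold, Robo4 3.76-fold and the BMP9 receptor Acvrl1 2.32-fold (median 0.39, camera adjusted p 0.00148, and adjusted p = 0.405 with an estimated correlation). Of 20 blood-brain barrier genes 9 rose, among them the transporters Slco1c1 (3.20-fold) and Slc2a1 (2.39-fold), and 3 fell, led by Itm2a (log2 fold change -1.67), with 14 passing when adjusted over the list alone. Slco1c1 lends its promoter to the Cre of the knockouts, and whether the construct adds to its counts was not tested. The barrier list's median of 0.24 did not pass (camera adjusted p 0.0789, and adjusted p = 0.647 with an estimated correlation), but the list blood-brain barrier passed without control 2 (0.00699), without knockout 2 (0.0145), with spots thinned to 1000 UMIs (0.00278), in region-matched sums (0.000172) and in sums matched over fixed region lists (0.00242).

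Mural cell genes rose as a list, while matrix genes went both ways. Among 15 mural cell markers 6 rose and 0 fell, 7 passing when adjusted over the list alone, with Tagln, a smooth-muscle cytoskeleton gene, up by 3.70 on the log2 scale and Mylk 2.16-fold (list median 0.25, camera adjusted p 0.0109, and adjusted p = 0.425 with an estimated correlation). Tagln was also among the leading genes of a clustered region named by the cortex list, with 383 and 474 knockout spots and 0 control spots. Its knockout change was lower in vessel-rich spots than in the rest (difference -1.93, given below). The rise of Tagln therefore need not concern mural cells. In the fibroblast and matrix list 13 of 29 genes rose and 8 fell, 23 passing when adjusted over the list alone. The basement-membrane collagens Col4a1 and Col4a2 rose 3.29-fold and 2.80-fold and the fibronectin gene Fn1 2.68-fold, and the 8 falls included the fibroblast genes Dcn (log2 fold change -1.16), Lum (-0.73) and Col1a2 (-0.69), singled out after their values were seen. Its median of 0.32 did not pass (camera adjusted p 0.0802, and adjusted p = 0.618 with an estimated correlation), though the list fibroblast and matrix passed without control 2 (0.00698), without knockout 1 (0.00333), with fry (0.0468), with spots thinned to 1000 UMIs (0.0137), in region-matched sums (0.00367) and in sums matched over fixed region lists (0.00196). Of the 10 genes of the CCM complex list, which holds Pdcd10 and its partners, Heg1 (2.03-fold) and Rasip1 (1.81-fold) rose and Stk26 fell (log2 fold change -0.64), and 3 passed when adjusted over the list alone. Stk26 did not pass without knockout 1 (-0.48, edgeR adjusted p 0.131) or in DESeq2 (-0.65, adjusted p 0.0604). The complex as a list had a median of 0.0043 (camera adjusted p 0.442, and adjusted p = 0.606 with an estimated correlation), though fry called it upward (adjusted p 0.00833).

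Interferon genes rose in every member tested, and reactive astrocyte genes in most. All 35 tested genes of the interferon response list rose, 35 also when adjusted over the list alone, with a median of 1.54 on the log2 scale (camera adjusted p 2.38e-18, and adjusted p = 0.284 with an estimated correlation). The membrane restriction factors Ifitm3 and Ifitm2 rose 3.10-fold and 3.22-fold, Lgals3bp 2.84-fold and the immunity-related GTPase Irgm1 3.02-fold. In the reactive astrocyte list 27 of 32 genes rose and only Tnc fell, 28 passing when adjusted over the list alone, and its median of 2.12 gave a camera adjusted p of 6.9e-15, and adjusted p = 0.284 with an estimated correlation. The intermediate filament gene Vim rose 11.9-fold to 480 ± 17.5 CPM, Fbln5 9.72-fold, and Serpina3n and Timp1 as given above. Of 15 general astrocyte markers 5 rose and 1 fell, 6 passing when adjusted over the list alone, with the gap-junction gene Gjb6 up 2.38-fold and Aldh1l1 up 1.74-fold. That list passed at a median of 0.23 (camera adjusted p 0.0250, and adjusted p = 0.623 with an estimated correlation) but not without control 1 (0.172) or without knockout 1 (0.155).

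Genes of complement, antigen presentation and cytokine signalling rose with them. Of 21 complement genes 17 rose and 1 fell, 18 passing when adjusted over the list alone (median 1.26, camera adjusted p 1.23e-08, and adjusted p = 0.352 with an estimated correlation). C4b, a component of the classical pathway, rose from 13.2 ± 1.55 to 107 ± 1.07 CPM, C1qb 2.39-fold, and the receptors for C3a and C5a, C3ar1 and C5ar1, 7.42-fold and 8.90-fold. C4b lies beside its near-identical copy C4a, so that their counts are uncertain where reads are shared. Antigen presentation had 16 rises and 2 falls among 22 genes, 20 passing when adjusted over the list alone, led by the class I genes H2-K1 (2.95-fold) and H2-D1 (2.83-fold), which also share sequence with their neighbours (median 1.04, camera adjusted p 8.22e-07, and adjusted p = 0.284 with an estimated correlation). Among 37 genes of chemokines, cytokines and adhesion 24 rose and 4 fell, 29 passing when adjusted over the list alone. Ccl12, a ligand for monocyte recruitment, rose 10.1-fold, Socs3 5.11-fold, Icam1 3.59-fold and Tlr2 4.08-fold (median 1.16, camera adjusted p 0.000281, and adjusted p = 0.405 with an estimated correlation).

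Phagocyte genes of an activated kind rose while those of resting microglia fell. In the activated microglia list 25 of 31 genes rose and 1 fell, 29 passing when adjusted over the list alone, among them osteopontin (Spp1, 8.20-fold), the actin-capping gene Capg (12.7-fold), Lgals3 (17.3-fold) and the lysozyme gene Lyz2 (4.52-fold). Its median was 0.93 (camera adjusted p 1.71e-11, and adjusted p = 0.284 with an estimated correlation). Of 16 homeostatic microglia genes 9 fell and 2 rose, 11 passing when adjusted over the list alone, with the purinergic receptor P2ry12 falling from 42.3 ± 5.07 to 12.8 ± 0.459 CPM and Gpr34, Siglech and Olfml3 at log2 fold changes of -1.42, -1.30 and -0.89. The list median was -0.64 (camera adjusted p 0.00518, and adjusted p = 0.585 with an estimated correlation). The list homeostatic microglia did not pass with spots thinned to 1000 UMIs (-0.43, camera adjusted p 0.274), in sums matched over fixed region lists (-0.42, 0.616) or with fry (0.0891). Its summed counts went the other way, from means of 4.64 and 5.38 UMIs per spot at 5000 UMIs in the controls to 9.55 and 8.21 in the knockouts. Sparc, its most abundant gene and also a matrix gene, singled out after its values were seen, rose from 436 and 592 CPM to 1462 and 1122. Among 13 neutrophil markers 10 rose and 1 fell, 12 passing when adjusted over the list alone, with the calprotectin genes S100a8 and S100a9 up 6.48-fold and 4.94-fold, and Retnlg, at 0.208 CPM in the controls, up 21.5-fold (median 2.33, camera adjusted p 0.000145, and adjusted p = 0.284 with an estimated correlation). Of 17 monocyte and border macrophage markers 10 rose and 2 fell, 12 passing when adjusted over the list alone, with Fcgr4 up 49.2-fold from 0.118 CPM and the scavenger receptor Stab1 up 2.99-fold (median 0.92, camera adjusted p 0.00088, and adjusted p = 0.405 with an estimated correlation).

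Genes of the coagulation and thrombosis list rose, and markers of platelets, lymphocytes and red cells did not pass camera as lists over whole sections. Of 30 coagulation and thrombosis genes 21 rose and 1 fell, 24 passing when adjusted over the list alone, at a median of 0.93 (camera adjusted p 5.89e-08, and adjusted p = 0.284 with an estimated correlation). The protease inhibitor A2m rose from 3.84 ± 0.944 to 58.8 ± 5.83 CPM, Anxa2, which binds plasminogen activator, 5.31-fold, Plaur, the urokinase receptor, 8.98-fold, and Pros1, the anticoagulant protein S gene, 3.89-fold. The list holds clotting and anticoagulant genes alike, so its rise gives no direction for clotting. Procr, Thbd and Vwf belong both to this list and to the CCM lesion vascular list. Other members stand in further lists, Cd9 and S100a10 in that of reactive astrocytes, Anxa2 in that of disease-associated oligodendrocytes and F13a1 in that of monocytes and border macrophages. Of 11 platelet markers 3 rose, Ppbp, Clec1b and Itgb3, 3 passing when adjusted over the list alone, and the median was 0.02 (camera adjusted p 0.404, and adjusted p = 0.585 with an estimated correlation), though fry called the list (adjusted p 0.0447). Of 14 lymphocyte markers 2 rose and 3 fell, 5 passing when adjusted over the list alone, with Trbc2 at a log2 fold change of -1.34 and Ighm at -1.13, and with Ccl5 at 1.72 but, without knockout 2, at 0.79 and not past edgeR's test (median -0.05, camera adjusted p 0.407, and adjusted p = 0.585 with an estimated correlation). Trbc2 was also among the leading genes of a clustered region named by the cortex list, with 427 and 434 control spots and 0 knockout spots. Its fall therefore need not concern lymphocytes. Among 6 erythrocyte markers Hba-a2 and Hba-a1 rose and Hbb-bt fell, 3 passing when adjusted over the list alone, and the haemoglobin genes are near-identical copies whose counts are uncertain. Hba-a1 did not pass without knockout 2 (0.22, edgeR adjusted p 0.281) or with spots of at least 2000 UMIs (0.40, 0.0676) or 5000 UMIs (0.15, 0.374), nor did Hbb-bt with spots thinned to 1000 UMIs (-0.43, 0.0741). The erythrocyte list had a median of -0.08, a mean of 0.05 and an upward camera direction (camera adjusted p 0.997, and adjusted p = 0.999 with an estimated correlation). The list erythrocyte passed camera upward with spots thinned to 1000 UMIs (median 0.95, adjusted p 0.0137) and downward in region-matched sums (median -0.74, adjusted p 0.0119).

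Myelin genes fell together. Of 20 myelin genes 18 fell, 1 rose and 1 did not pass, 19 passing when adjusted over the list alone, at a median of -1.23 (camera adjusted p 1.26e-10, and adjusted p = 0.416 with an estimated correlation). Mog, the myelin oligodendrocyte glycoprotein, fell from 199 ± 26.4 to 40.3 ± 4.73 CPM, and Ugt8a, which makes the galactolipids of myelin, fell by 2.27 on the log2 scale. Apod, the lipid carrier apolipoprotein D, rose from 320 ± 49.9 to 1508 ± 75.1 CPM. Among 12 oligodendrocyte precursor markers 8 fell and 2 rose, 10 passing when adjusted over the list alone, with the differentiation receptor Gpr17 at a log2 fold change of -1.19 and the lineage factors Sox10 and Olig1 at -0.76 and -0.78 (median -0.58, camera adjusted p 0.00525, and adjusted p = 0.557 with an estimated correlation). In the list of disease-associated oligodendrocyte genes 10 of 14 rose and 1 fell, 12 passing when adjusted over the list alone, with Serpina3n and C4b as above, the cell-cycle inhibitor Cdkn1a up 5.95-fold and Anxa2 up 5.31-fold (median 0.92, camera adjusted p 6.78e-06, and adjusted p = 0.405 with an estimated correlation). Its members Serpina3n, C4b, H2-K1, H2-D1 and B2m also stand in the lists of reactive astrocytes or antigen presentation.

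Activity-induced genes of neurons fell, and neuronal markers went both ways. Of 23 immediate early genes 18 fell and 3 rose, 21 passing when adjusted over the list alone, at a median of -1.33 (camera adjusted p 7.74e-09, and adjusted p = 0.405 with an estimated correlation). Arc, a regulator of synaptic receptors, fell by 2.51 on the log2 scale and Nr4a1 from 159 ± 7.61 to 26.2 ± 0.325, while Jun, Ptgs2 and Ier3 rose. In the synapse list 9 of 26 genes fell, among them Stx1a (log2 fold change -0.71) and Rims1 (-0.68), and 3 rose, among them Cplx2 (0.48), with 12 passing when adjusted over the list alone. The synapse median of -0.08 passed narrowly (camera adjusted p 0.0449, and adjusted p = 0.497 with an estimated correlation), and the list synapse did not pass without control 2 (0.0924), without knockout 1 (0.1002) or with spots thinned to 1000 UMIs (0.305). Of 12 excitatory neuron markers 6 fell and 2 rose, 8 passing when adjusted over the list alone, with the cortical gene Neurod6 at -0.91 and Nptx1 at 0.78 (median -0.19, camera adjusted p 0.0828, and adjusted p = 0.405 with an estimated correlation). Of 12 inhibitory neuron markers Lamp5 (log2 fold change -1.70), Sst (-0.67), Slc32a1 (-0.52) and Calb2 (-0.63) fell and Npy (1.15) rose, 5 passing when adjusted over the list alone. That list had a median of 0.0091 but a mean of -0.17 and a downward camera direction (camera adjusted p 0.404, and adjusted p = 0.618 with an estimated correlation).

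Metal-handling and lysosomal genes rose, and nuclear genes of respiration fell. Of 22 genes of iron and heme handling 15 rose and 2 fell, 18 passing when adjusted over the list alone, with heme oxygenase 1 (Hmox1) up 4.59-fold, the ferroxidase Cp 2.63-fold and the metallothionein Mt1 from 1706 ± 136 to 5748 ± 625 CPM (median 0.50, camera adjusted p 0.000165, and adjusted p = 0.405 with an estimated correlation). Of 26 lysosomal genes 16 rose and 2 fell, 18 passing when adjusted over the list alone, with the cathepsins Ctsh and Ctsc up 3.66-fold and 2.48-fold and progranulin (Grn) 1.98-fold (median 0.34, camera adjusted p 5.79e-06, and adjusted p = 0.405 with an estimated correlation). In the hypoxia response list 15 of 29 genes rose and 2 fell, 17 passing when adjusted over the list alone. Adrenomedullin (Adm) rose 9.22-fold and Angptl4 3.20-fold, the carbonic anhydrase Car9 went from 0.0877 to 1.43 CPM, and the glucose transporter Slc2a1, which is also a barrier gene, rose 2.39-fold (median 0.27, camera adjusted p 0.000924, and adjusted p = 0.284 with an estimated correlation). Among 26 nuclear genes of oxidative phosphorylation 17 fell and 0 rose, 18 passing when adjusted over the list alone, with Atp5k at -0.61 and Uqcrb at -0.65, and Cox6c at -0.59 but not past the test without knockout 2 (-0.54, edgeR adjusted p 0.0563; list median -0.37, camera adjusted p 8.88e-07, and adjusted p = 0.497 with an estimated correlation). None of the 13 mitochondrial transcripts passed edgeR's test, 0 also when adjusted over the list alone, with mt-Nd2 at -0.58 (edgeR adjusted p 0.0785) and mt-Nd4 at -0.50 (edgeR adjusted p 0.0895), which passed without control 1 (1.12e-06 and 3.57e-06), with no filter on low counts (4.33e-07 and 1.59e-05) and with spots thinned to 1000 UMIs (0.00353 and 0.00480), and mt-Nd2 also with crossed replicate numbers as a block (0.0372). Their list median was -0.21 (camera adjusted p 0.390, and adjusted p = 0.826 with an estimated correlation), at -0.52 without control 1 (1.58e-06), at 0.14 without control 2 (0.0388), at -0.41 with thinned spots (0.00138) and at -0.26 in region-matched sums (0.000221).

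As lists in camera with the preset correlation, cell cycle genes rose, and genes of stress and of sterol synthesis fell. With fry the lists of the cell cycle (adjusted p 0.0772) and of cholesterol synthesis (0.0626) did not pass. Of 22 cell cycle genes 12 rose and 2 fell, 15 passing when adjusted over the list alone, with Ccnd1 up 2.37-fold, Ube2c 4.71-fold and Cdk1 4.86-fold, and Ccnd2 at a log2 fold change of -0.66 (median 0.66, camera adjusted p 0.00532, and adjusted p = 0.506 with an estimated correlation). Of 19 genes of heat shock and ER stress 13 fell, among them Cryab (-1.11) and Atf4 (-0.79), and 2 rose, the small heat shock protein Hspb1 4.16-fold and Trib3 5.54-fold. There 15 passed when adjusted over the list alone (median -0.38, camera adjusted p 0.00173, and adjusted p = 0.405 with an estimated correlation). Of 20 genes of cholesterol synthesis 9 fell and 1 rose, 12 passing when adjusted over the list alone, with Dhcr7 at -0.75 (median -0.21, camera adjusted p 0.00202, and adjusted p = 0.440 with an estimated correlation).

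Markers of the brain's linings fell or went both ways. Among 12 leptomeningeal markers 6 fell and 0 rose, 8 passing when adjusted over the list alone, with the transporters Slc22a6 and Slc13a4 at log2 fold changes of -1.77 and -1.56 (median -0.61, camera adjusted p 0.00652, and adjusted p = 0.497 with an estimated correlation). Of 11 choroid plexus markers 4 fell, among them Ttr and Enpp2 (-1.10), and Otx2 rose (0.86), 7 passing when adjusted over the list alone. The choroid plexus median of -0.54 did not pass (camera adjusted p 0.0828, and adjusted p = 0.405 with an estimated correlation), but the list choroid plexus passed without control 1 (0.0145), without knockout 2 (0.0167), with fry (0.0400), with the replicate block (0.0320), with spots thinned to 1000 UMIs (0.0248) and in sums matched over fixed region lists (0.000288). With thinned spots Otx2 was at 0.33 and not past the test (edgeR adjusted p 0.544). Of 9 ependymal markers Tmem212 (-2.59), Ccdc153 (-1.97) and Mia (-0.74) fell and Rarres2 (1.31) and Tm4sf1 (0.67) rose, 6 passing when adjusted over the list alone (median -0.18, camera adjusted p 0.390, and adjusted p = 0.618 with an estimated correlation).

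In all, 28 of the 39 lists passed camera with a preset correlation of 0.01, 19 up and 9 down. With a correlation estimated per list, camera called 0 lists, 4 had an unadjusted p under 0.05, and fry, which does not set a list against other genes, called 24, of them 19 that had passed camera. It did not call those of mural cells (adjusted p 0.0677), cell cycle (0.0772), cholesterol synthesis (0.0626), leptomeninges (0.0954), oligodendrocyte precursors (0.129), oxidative phosphorylation (0.0954), astrocytes (0.294), the synapse (0.0772) and homeostatic microglia, and it added those of excitatory neurons (0.0206), platelets, the CCM complex, choroid plexus and matrix. In 163 spots per library matched over regions 12 and 13, the regions found in all 4 libraries, 20 lists could be tested. There 14 lists passed, 10 of them among the 14 tested that had passed over whole sections, and those of activated microglia (adjusted p 0.288), astrocytes (0.374), the lysosome (0.243) and the synapse (0.381) did not in camera. Sums matched over the fixed region lists called 27 of 36 lists, and those of homeostatic microglia (adjusted p 0.616), chemokines, cytokines and adhesion (0.0730) and the synapse (0.268) lost their calls in camera.

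**Figure D2:**
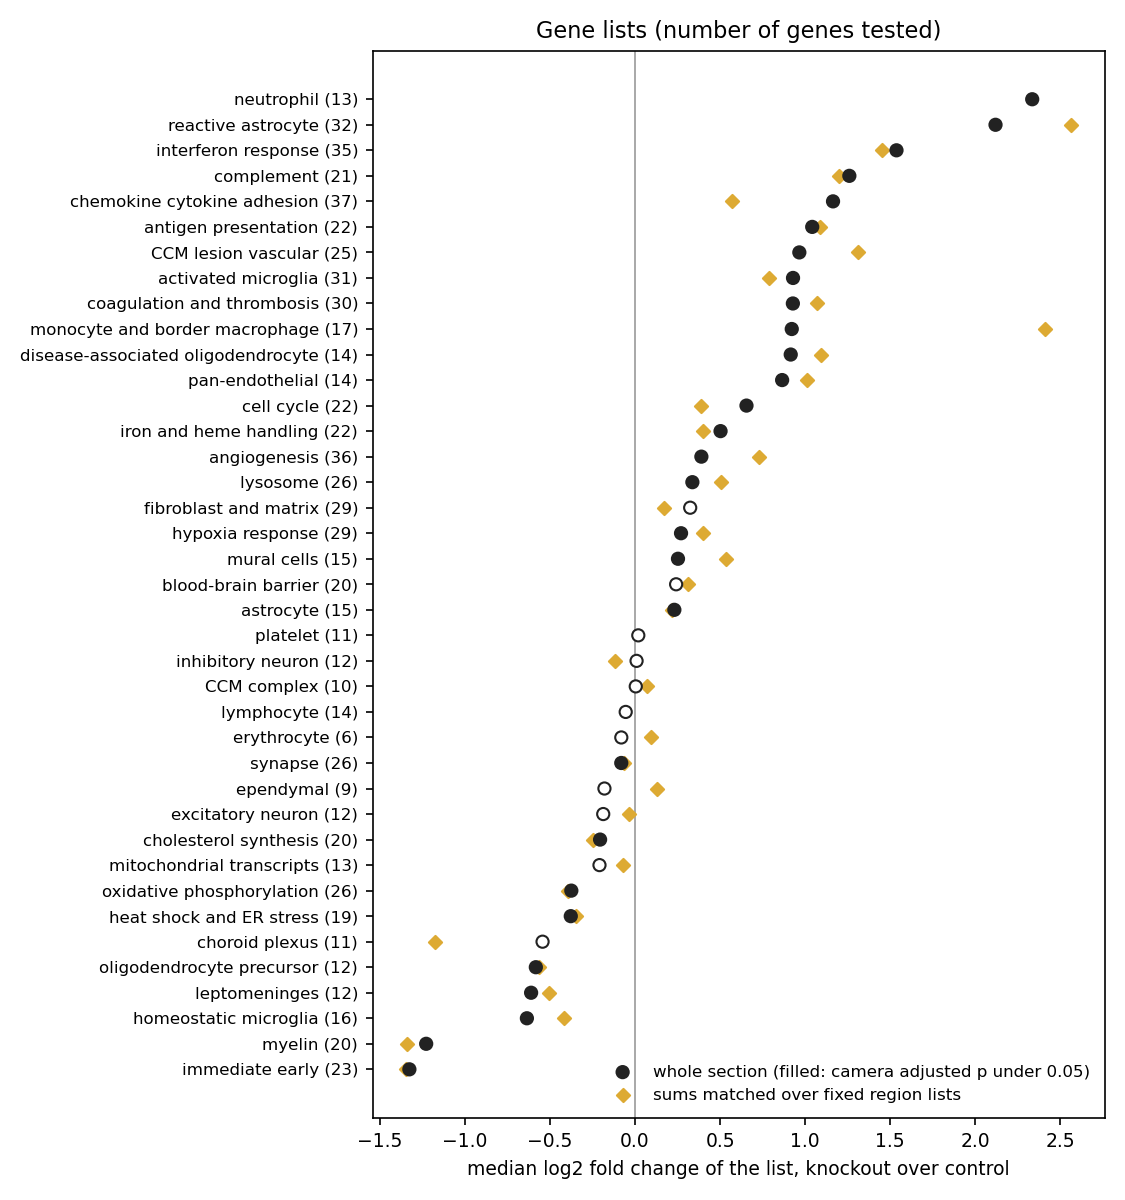
Median log2 fold change (knockout over control) of the 39 gene lists, with the number of genes tested in brackets. Circles are whole-section sums, filled where the camera adjusted p was under 0.05, and diamonds are sums matched over the fixed region lists, where myelin stood at -1.34, immediate early genes at -1.35 and reactive astrocyte genes at 2.57.

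Several lists kept their direction in spots of all 8 fixed region lists, but not in every region found by clustering. In spots assigned to the 8 fixed region lists, the median of the reactive astrocyte list ran from 1.22 (midbrain and hindbrain) to 3.15 (cortex), that of interferon genes from 0.60 to 2.55, that of the CCM lesion vascular list from 0.74 to 1.66 and that of pan-endothelial markers from 0.57 to 1.28. Myelin genes lay between -1.74 (olfactory bulb) and -0.92 (striatum), and immediate early genes between -1.93 (cortex) and -0.20 (midbrain and hindbrain). In spots of the cortex list Vim was higher by 5.08 on the log2 scale (SE 0.159) and Serpina3n by 6.55 (SE 0.123), and in spots of the cerebellum list by 3.19 (SE 0.135) and 4.71 (SE 0.164). In region 12 of the clustering, activated microglia genes had a median of -0.18 (5 rose and 4 fell), complement genes -0.21 (3 and 4) and immediate early genes -0.14 (3 and 3). Of 16 homeostatic microglia genes 14 fell and 1 rose in region 12 (median -1.88), and in region 13 3 of 15 fell and 1 rose (median -0.49). Their medians in spots of the 8 fixed region lists ran from -1.15 to -0.16. The 4 neutrophil genes tested in region 13 fell (median -3.45), and of 5 in spots of the hypothalamus and amygdala list 0 rose and 1 fell in edgeR's test. Differences between regions were not tested, and the assignment did not even out the sections. In sums matched over these lists 41 of 84 tested region genes still passed edgeR's test, against 51 of them over whole sections. Their median absolute log2 change was 0.499, against 0.4425 over whole sections. In the matched sums 2329 of 12031 genes passed.

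**Figure D3:**
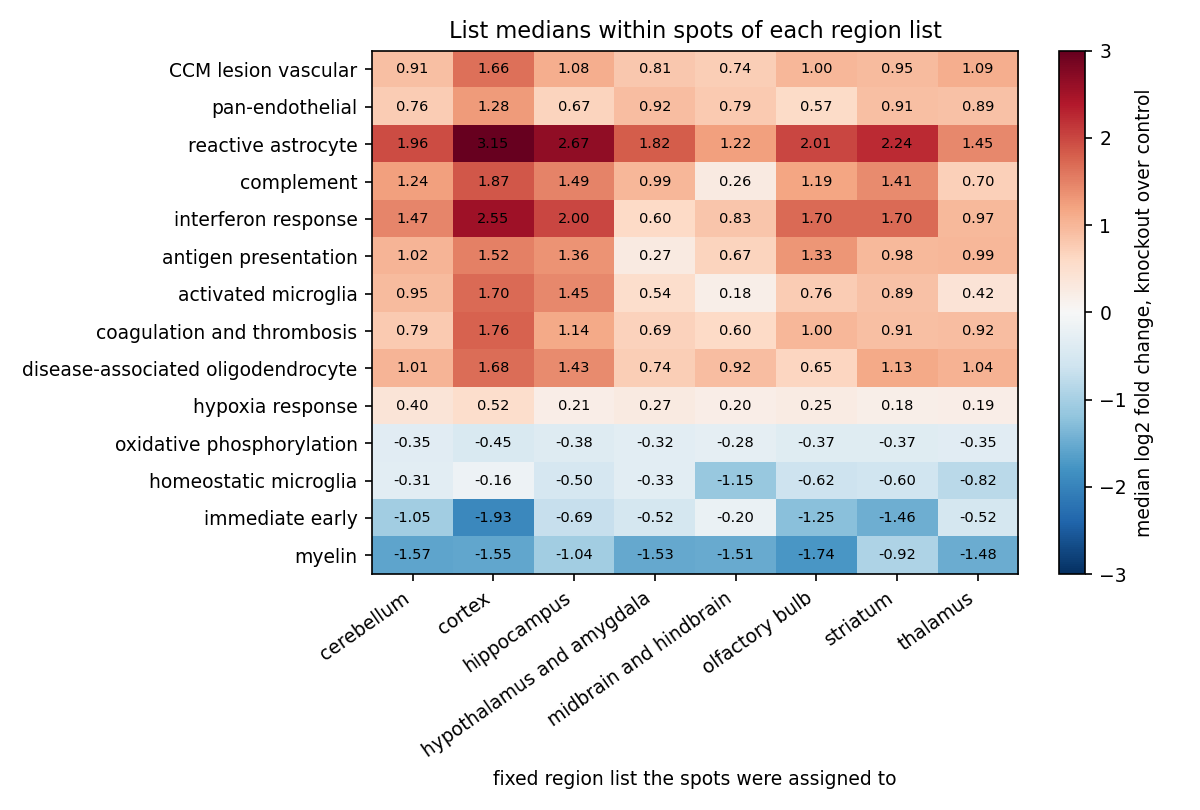
Median log2 fold change (knockout over control, colour and number) of 14 gene lists in spots assigned to each of 8 fixed region lists. Reactive astrocyte medians lie between 1.22 and 3.15, and myelin medians between -1.74 and -0.92.

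Within regions found by clustering in all 4 libraries, 1797 genes passed in at least 1 region. Region 12, led by the dopamine-neuron genes Slc6a3, Th and Slc10a4 and named by the midbrain and hindbrain list, held 108 and 109 control spots and 192 and 192 knockout spots. In it 1572 of 12295 genes passed, 686 higher and 886 lower. Opalin (log2 fold change -3.81), Ugt8a (-2.72) and Pllp (-2.78) of myelin fell there, as did Pth2 (-5.97), and Rprm (4.01) rose, with edgeR adjusted p from 2.64e-12 to 2.07e-11. Region 13 stays unnamed, because pituitary and choroid plexus genes (Prl, Cga, Ttr and Gh) led it although its list was that of the hypothalamus, and it held 189 and 210 control spots and 55 and 145 knockout spots. There 455 of 12786 genes passed, 329 higher and 126 lower, with Agrp (-6.97) and Pomc (-5.03) lower and Pglyrp1 (4.18), Sat1 (2.69) and Ly6a (2.79) higher at edgeR adjusted p from 6.47e-07 to 2.31e-05. DESeq2 called 757 genes within these regions.

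Sums of equal numbers of spots from these regions, thinned to equal depth, left 145 of 3553 genes past edgeR's test, 71 higher and 74 lower. Serpina3n (log2 fold change 3.47), Pglyrp1 (3.78), Ly6a (2.61), Sat1 (2.59) and Apod (1.88) rose, and the myelin genes Mog (-2.33) and Mag (-2.02) fell, as did Ttr and Gh, although Ttr did not pass without control 1 (edgeR adjusted p 0.292) or in DESeq2 (0.0645), nor Serpina3n at a Leiden resolution of 1.0 (2.23, edgeR adjusted p 0.0596). Adjusted p ran from 2.32e-72 to 7.76e-12 in edgeR's quasi-likelihood test. Values this small from 2 libraries per group rest on spread pooled over genes, so they do not measure how far each gene varied between libraries. The count fell with each library left out, to 81 without control 1, 65 without control 2, 69 without knockout 1 and 66 without knockout 2, and to 29 in DESeq2. With all 4 libraries and another seed for the draw of spots it was 66, so the falls cannot be laid to the library left out. With no filter on low counts it was 0 in edgeR, where 707 genes had an unadjusted p under 0.05.

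Spots rich in endothelial RNA were compared with the rest of each section, to ask whether the knockout change differs there. In vessel-rich spots, the 10% of a library's spots with the largest share of pan-endothelial UMIs, the knockout change of Cd34, a surface protein of endothelium, was higher by 1.25 on the log2 scale, that of the phosphatase gene Dusp1 by 1.36 and that of the antioxidant gene Gpx3 by 1.68. It was lower for Vim (-1.02), Fbln5 (-1.83), Tagln (-1.93), Igfbp2 (-1.03) and A2m (-1.60), which rose over the section as a whole, and for the hypothalamic peptide genes Cartpt (-1.89) and Pomc (-2.74). In all 60 of 17151 genes passed the test of the difference, 37 with a higher and 23 with a lower log2 change, at edgeR adjusted p of 0.000347 (Cartpt) to 0.00205 (Dusp1) for the genes named. Of 23 immediate early genes, most of which fell over whole sections, 7 had a higher log2 change there and 0 a lower one (median difference 0.58), and of 32 reactive astrocyte genes 0 and 4. The cut was made within each library, so the class differed in endothelial content between the groups. Vessel-rich spots held 8.09 and 8.26 pan-endothelial UMIs per 10000 in the controls, and 18.4 and 20.1 in the knockouts. This unequal content cannot be told apart from a knockout change that differs near vessels. Vessel-rich spots were shallow in control 2, with a median of 1670.5 UMIs against 17501.5 in the rest, and with spots of at least 5000 UMIs 53 genes passed, 44 of them the same genes in the same direction. The count was 28 without control 1, 97 without control 2, 202 without knockout 1 and 130 without knockout 2.

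Spots with high counts of lesion-type vascular genes were far more frequent in the knockouts. At 5000 UMIs per spot, 22 of 2267 and 19 of 2557 control spots held more than 7 UMIs of the CCM lesion vascular list, a limit set at the higher of the controls' 99th percentiles. The shares were 0.970% (95% Wilson interval 0.642 to 1.47) and 0.743% (0.476 to 1.16). In the knockouts 250 of 2952 spots, 8.47% (7.52 to 9.53), and 308 of 3468 spots, 8.88% (7.98 to 9.87), lay above it, and these intervals cover counting error only. The mean was 8.68% ± 0.292 (SD, n = 2), and the exact permutation test of 2 against 2 cannot give a two-sided p under 0.33. Without Ly6a and Cdh2, the most abundant genes of the list, the mean share was 3.54% against 0.617% in the controls. For pan-endothelial markers, with a limit set in the same way, the mean share was 7.73% in the knockouts against 0.607% in the controls. The shares therefore do not part lesion-type genes from endothelial RNA in general. Above limits set in the same way lay 19.6% of knockout spots for the disease-associated oligodendrocyte list, 17.9% for reactive astrocytes, 13.7% for iron and heme handling, 10.3% for the lysosome, 9.46% for complement, 8.13% for interferon genes and 4.88% for coagulation. The iron and heme counts include the abundant metallothionein gene Mt1, which rose from 1706 to 5748 CPM, so that share need not concern iron. For chemokines, cytokines and adhesion it was 0.169% in knockout 1 and 1.70% in knockout 2, against 0.794% and 0.743% in the controls. For the immediate early list it was 0 of 2952 and 0 of 3468 knockout spots, against 22 of 2267 and 11 of 2557 control spots. For the oxidative phosphorylation list it was 0 in both knockouts and also 0 of 2557 in control 2, and the 20 spots above the limit all came from control 1.

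**Figure D4:**
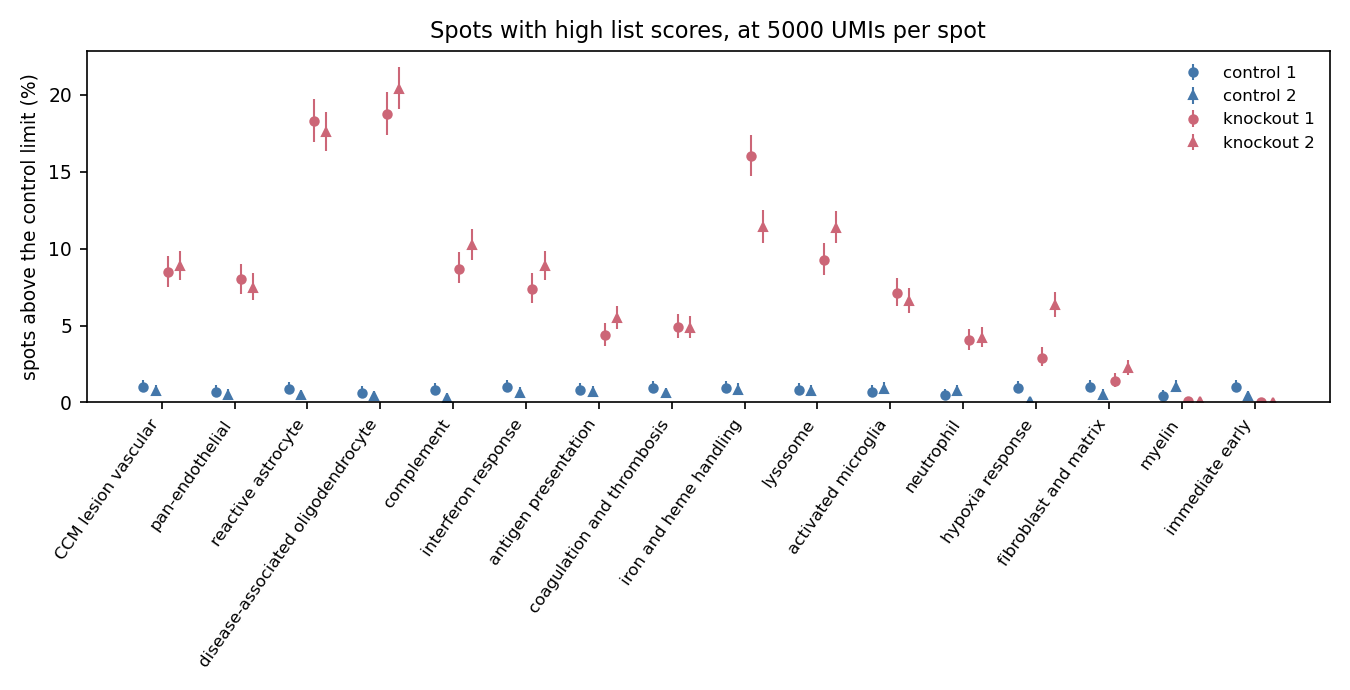
Percent of spots of at least 5000 UMIs, thinned to that depth, that lie above the controls' limit for 16 gene lists, with 1 point per library and 95% Wilson intervals. Knockout shares reach 17.9% for reactive astrocyte genes on average, and control shares lie near 1% or lower because the limit was set on them.

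Within the knockout sections, lesion-score spots were rich in endothelial RNA, as they were within the controls. The class was cut on a list that holds endothelial genes such as Vwf, Nos3 and Procr. Higher levels of other endothelial genes therefore follow at least in part from the selection, also with genes of that list left out of the calls. Against the other spots of the same libraries, Cldn5 was higher by 1.71 on the log2 scale, Flt1 by 1.61, Ly6c1 by 1.87, Podxl by 1.92 and Adgrl4 by 1.60, all genes of endothelium. The proteoglycan gene Srgn was higher by 1.90, Igfbp7 by 1.70, Ctla2a by 1.52 and Pglyrp1, an antibacterial protein, by 1.67. Each had an edgeR adjusted p between 9.55e-19 and 3.63e-17. All 14 pan-endothelial markers were higher, as were 18 of 20 barrier genes, 24 of 29 matrix genes, 11 of 12 leptomeningeal markers (median 2.56), 28 of 35 interferon genes and 17 of 24 clotting genes, while 20 of 26 synapse genes were lower. Of neutrophil markers 1 of 11 passed as higher, of lymphocyte markers 2 of 10 and of genes of chemokines, cytokines and adhesion 15 of 36. Of 16666 genes 2986 passed edgeR's test, 1911 higher and 1075 lower. The same contrast within the controls, over 41 spots, called 2657 genes, and 1546 of the 1551 called in both had the same direction. Medians in the controls were 1.97 for pan-endothelial markers (1.68 in the knockouts), 2.04 for interferon genes (0.96) and 4.06 for leptomeningeal markers, and the difference was not tested. Without knockout 1 the count was 613, without knockout 2 it was 166, and DESeq2 called 837.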

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

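The tests of explanations in this part were chosen after the result was seen, except that of vascular RNA for the hypoxia list.

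The genes here drew attention because a test of the interaction between genotype and spot class found their knockout change to differ between vessel-rich and other spots. The difference in log2 change was -1.89 for Cartpt, whose vessel-rich spots stood at -2.30 against the rest in the knockouts and -0.41 in the controls. It was -1.02 for Vim (1.02 in the knockouts, 2.05 in the controls), -1.83 for Fbln5 (0.72 and 2.55), -1.93 for Tagln (0.98 and 2.91) and -1.03 for Igfbp2 (0.83 and 1.86). For Pomc it was -2.74 (-0.39 and 2.35), for A2m -1.60 (1.39 and 2.99), for Gpx3 1.68 (1.36 and -0.32), for Cd34 1.25 (1.70 and 0.45) and for Dusp1 1.36 (1.09 and -0.26). All 10 also passed with spots of at least 5000 UMIs, at differences from -2.53 to 1.35. The spot classes of a library share its tissue, and vessel-rich spots were shallower than the rest in every library.

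Myelin genes fell over whole sections, 18 of 20 past edgeR's test. Fewer oligodendrocytes, each with its RNA as before, would lower alike those members that only oligodendrocytes express. Of the 20 members 11 lay over 2 standard errors from the list median, and Apod rose. Members that other cells also express would depart from the median too, so this spread cannot decide for or against that account. Sections from different brain regions remain open: the highest of the 8 medians in spots assigned to a fixed region list was -0.92, a fall in each, but region genes had a median absolute log2 change of 0.499 in sums matched over these lists, no less than the 0.4425 over whole sections. In region 12, where the myelin median was -1.64, 29 of 72 region genes passed edgeR's test as well. A change within oligodendrocytes of the knockout mice stays open as well, as a hypothesis that these spots of mixed cells cannot settle.

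Immediate early genes fell, 18 of 23 past edgeR's test. Their median in spots of fixed region lists ran up to -0.20 in the midbrain and hindbrain and was -1.93 in the cortex. Different regions in the sections may thus account for a part and cannot be told apart from the rest, since matching left the median change of region genes no smaller than before. Activity or handling of the mice before freezing could also move these genes quickly, and the larger of the within-group differences was 0.12, against -1.28 between groups. A handling difference shared by both libraries of a group would leave no trace in that value, so it cannot be told apart from genotype.

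Hypoxia-response genes rose, 15 of 29 past edgeR's test. More vascular RNA in the knockout sections went with the order of these genes. Across genes, the knockout change correlated with the excess in vessel-rich spots of the knockouts at a Spearman rho of 0.459 (29 genes, permutation p 0.0126). The Pearson r was 0.618 (permutation p 0.0013). Genes are not independent replicates, and both quantities use the same knockout libraries. Over spots, a comparison chosen after the data were seen, counts of the list did not rise with the lesion score. There rho was -0.153 and -0.0926 in the controls and -0.0229 and -0.0929 in the knockouts. Summed counts weigh abundant genes most, so this rho says little about the genes that rose. Gene by gene, 10 of 29 were higher and 2 lower in lesion-score spots of the knockouts in edgeR's test (median 0.13). Within the controls 4 were higher and 6 lower (median -0.295). More vascular RNA thus stays open as an account. Low oxygen, as 1 label of the knockouts says, stays open: the median of 10 glycolysis and mitochondria genes of the list was 0.0465, with 3 that rose and 0 that fell in edgeR's test. The label coincides with genotype in every library, so the oxygen level and the deletion cannot be told apart.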

How the results depend on the processing

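Alternatives added after the data were seen were spots of at least 5000 UMIs, fixed region lists, the lesion list without Ly6a and Cdh2, and crossed numbers. Of 2355 comparisons for 158 genes named over whole sections, 2334 kept direction and side of the threshold, 14 lost the call, 7 gained it and 0 reversed. For lists 399 of 483 did so. The genes named for lesion-score spots, vessel-rich spots and regions 12 and 13 did so in all comparisons run, and those of region-matched sums in 107 of 119. In region-matched sums, of 163 spots per library thinned to 1000 UMIs, simulated 2-fold changes were found in 28.7% of cases, against 90% over whole sections. Except where said, the cause was not tested.

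The replicate block, which takes the replicate numbers of the titles as pairs, called 5813 genes over whole sections, 116 in region-matched sums and 29 lists. Nothing in the labels pairs the libraries, and same-numbered libraries deviated from their group means with a correlation of -0.23 across genes, so the numbers were not used as pairs. Crossed numbers called 8176 genes.

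Over whole sections, 3193 genes passed with spots thinned to 1000 UMIs, where fewer were tested. Region-matched sums gave 29 with DESeq2, 0 with no filter on low counts (707 at an unadjusted p under 0.05 in edgeR), 66 with another seed, 92 at resolution 0.3, 54 at 1.0, 1520 with expression centred per library, 86 with spots of at least 500 UMIs and 2329 with fixed region lists, and the last and the centred regions held more spots by construction. Within regions it was 757 with DESeq2, 3136 at resolution 0.3, 923 at 1.0, 7742 centred and 8854 with fixed region lists. Vessel-rich spots gave 242 with no filter and 38 with at least 2000 UMIs. Lesion-score spots gave 837 with DESeq2 and 1307 thinned to 2000 UMIs. An estimated correlation called 0 lists in camera (4 at an unadjusted p under 0.05, fry 24), and region-matched sums 14. The mean knockout share above the lesion limit was 13.4% and 20.4% at the planned lower percentiles, 5.12% thinned to 2000 UMIs and 3.54% without Ly6a and Cdh2. Overlap of region shares between groups was 4.15% at resolution 0.3, 44.9% centred, 1.19% with at least 2000 UMIs and 79.9% with fixed region lists.

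The direction in camera, which can part from the sign of the median, turned with these medians: for the list erythrocyte, -0.11 and -0.22 with at least 2000 and 5000 UMIs and -0.74 in region-matched sums; for the list ependymal, -0.0077 thinned to 1000 UMIs and 0.13 over fixed region lists; for the list excitatory neuron, 0.066 thinned and 0.0060 region-matched; for the list synapse, 0.12 region-matched.

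With each library left out, counts ran from 4924 to 7182 over whole sections, 65 to 81 in region-matched sums, 1229 to 1816 within regions, 28 to 202 in vessel-rich spots, 166 to 3794 in lesion-score spots and 27 to 30 for lists. Pdcd10 ran from -0.16 to -0.01, the list erythrocyte from -0.22 to 0.047 and the list mitochondrial transcripts from -0.52 to 0.14. Region-matched sums and tests within regions gave no value with spots of at least 2000 UMIs, where no region was shared, and lesion-score spots none with 500 or 2000, since they hold at least 5000.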

Other observations

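The neighbours of Slco1c1, the correlations over spots and the assignment by fixed region lists were chosen after the data were seen, and the values are given without explanation. Slco1c1, the gene whose promoter drives the Cre of the knockouts, lies on chromosome 6 and was at 42.5 and 45.7 CPM in the controls and 148 and 135 in the knockouts (log2 fold change 1.68). Of its neighbours, the phosphodiesterase gene Pde3a was at 4.09 and 4.02 CPM against 18.7 and 18.0 (2.17), Gm6614 was at 0 and 0 CPM against 0.631 and 0.975, Slco1a5 rose by 3.47, Slco1a4 by 0.45, and Plekha5 and Aebp2 stood at 0.04 and 0.10. Over spots, counts of the pan-endothelial list correlated with the lesion score at a Spearman rho of 0.128 and 0.0974 in the controls and 0.351 and 0.373 in the knockouts, and those of the reactive astrocyte list at 0.113 and 0.110 against 0.298 and 0.261. Other lists went otherwise. The hypoxia response list was at -0.153 and -0.0926 against -0.0229 and -0.0929, and the synapse list at -0.136 and -0.0787 against -0.159 and -0.221. Leptomeningeal markers were at 0.180 and 0.128 against 0.0568 and 0.119. Spots are not independent replicates.

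By the fixed region lists, the hippocampus list took 14.6% and 14.6% of control spots and 17.6% and 22.3% of knockout spots, the olfactory bulb list 11.6% and 10.3% against 15.1% and 15.6%, the cerebellum list 7.15% and 7.47% against 4.98% and 3.72%, and the hypothalamus and amygdala list 10.5% and 12.0% against 8.03% and 8.16%. Spots above the controls' limit for the white matter list were 0.709% of control spots and 0% of knockout spots on average. Homeostatic microglia genes, lower as a list over whole sections, had 7.35% of knockout spots above their limit against 0.952% of control spots. These counts include Sparc, the list's most abundant gene and also a matrix gene, which rose, so the share need not concern microglia.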
